A study of Mus musculus with 6 samples.

How the data were processed

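RNA from 3 lacrimal gland samples of ICR mice and 3 of NOD/Ltj mice was measured by RNA sequencing, with 1 library per sample. Per the labels' protocols, polyadenylated RNA was selected, the library was made strand-specific by dUTP labelling of the second strand, and 2 × 150 bp paired-end reads were sequenced. The submitters' processing notes name fastp, StringTie and edgeR, with no versions or roles. The aligner, the genome build, the way counts were derived and the strand setting of the counting are not given in the sources used here. Genes that overlap or lie antisense to another gene are therefore uncertain, since reads of both partners may have been counted together. The labels give replicate numbers and do not say that each sample came from a separate animal, so p-values measure the spread between these samples. The labels also give neither age nor sex, so a difference in age between the strains was not tested and stays open for every difference reported.

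The authors deposited a table of estimated counts per gene for the 6 libraries, which were already whole numbers and not scaled between libraries. The test had been planned for plain counts. Since the values were whole, nothing was rounded and the planned count test was kept. Low values piled up at multiples of 4: between 30.4 and 31.7% of the values from 1 to 40 were such multiples, where 25% would be without steps, and ICR 1 held 368, 808 and 223 genes at 3, 4 and 5 counts. A fragment thus added about 4 counts to a gene with few reads. A count of 0 allows up to 3 fragments at 95% confidence, or 12 counts per library, which is 0.157 to 0.205 CPM before scaling. That floor covers counting error only, since reads carried no molecular identifiers. A fold against a group with 0 counts in every library is given as a lower bound against this floor.

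The table held 55401 gene identifiers, of which 26034 were at 0 in every library. A symbol from the gene name table of GENCODE mouse release 21 matched 55141 of them. The 260 without a symbol held 0.0037 to 0.0106% of the counts, and 106 symbols stood on several identifiers. No coordinates are printed, since the build of the counts was not given. The release served only for names, for which genes neighbour each other and for transcript sequences. Families with near-identical members (the secretoglobins, Obp, Mup and H2 genes, Tgtp1 and Tgtp2, Rps2 and its processed copies, and Cwc22 and its copies) are uncertain, since the counting could split reads among them. To look for libraries deposited more than once, each pair was compared by chi-square over genes. The values ran from 38.5 to 381 per degree of freedom, so each library was counted as 1 sample.

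Differences were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with TMM scaling and the filterByExpr filter, two-sided and without a block. P-values were adjusted by the Benjamini-Hochberg method over the 18537 genes tested, and a gene was called at an adjusted p under 0.05. TMM factors ran from 0.809 (ICR 2) to 1.25 (NOD 2). Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries, and log2 fold changes are NOD/Ltj over ICR with their standard error. This error was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.421. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over 43 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it.

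The comparison, the tests, the lists and the rule for naming genes were fixed before the data were examined. Besides NF-κB signalling components and NF-κB target genes, the lists covered the TNF superfamily, Toll-like receptors and the inflammasome, both interferon responses, both MHC classes, chemokines, lymphoid neogenesis, complement and cathepsins. Marker lists covered T cells, regulatory and helper T cells, cytotoxic cells, B cells, plasma cells, monocytes and macrophages, dendritic cells, and neutrophils and mast cells. Lists of the gland covered acinar, ductal and myoepithelial cells, secretagogue receptors, exocytosis and hormone receptors. Lists of stroma and neighbouring tissue covered extracellular matrix, endothelium, adipocytes, salivary glands, Harderian and sebaceous glands, skeletal muscle, nerve and erythrocytes. Lists of cell state covered the unfolded protein response, apoptosis, the cell cycle, oxidative phosphorylation, mitochondrial transcripts, ribosomal proteins, lipid synthesis, immediate early genes and sex-linked genes.

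The naming rule took the 12 largest increases and the 12 largest decreases among called genes with an absolute log2 fold change of at least 1, groups that did not overlap and a mean of at least 5 CPM in a group (236 higher and 27 lower genes were eligible). It left out genes without a symbol, symbols of the Gm, Rik and -ps kinds, and variable, diversity and joining segments of antigen receptors. It also took the 4 called members with the smallest adjusted p of each list, or the member with the smallest p where none was called. Nfkb1, Nfkb2, Rela, Relb, Rel, Nfkbia, Tnfaip3, Ikbkb, Tnf, Il1b and Il6 were always taken, as were Hc, H2-Ea, Xist and Ddx3y as checks of strain and sex. The rule gave 106 genes, of which 70 were called, and not all are printed. Results for some genes are not reported here. Hc stood at 0.372 ± 0.092 CPM in ICR and 0.221 ± 0.115 in NOD/Ltj (SD, n = 3 each, adjusted p = 0.716), and H2-Ea was not analysed here under that symbol. Genes named outside the rule were chosen after their values were seen. These were Foxp3, Cd86, Btrc, Cd4, Cd8a, Ccl19, Ccl21a, Cxcl13, Igha, Jchain, Igkc, Obp1a, Obp1b, C130026I21Rik, Gm16028, and members named only for passing when adjusted over their list alone.

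The test was checked on simulated counts for the comparison of NOD/Ltj with ICR, with 17889 genes tested and 200 genes changed. It called 7.5% of 67 genes changed 2-fold, 68.7% of 67 changed 4-fold and 87.9% of 66 changed 8-fold, and 5 of 17649 unchanged genes. Estimated against true changes had a slope of 0.997. A planted list of 40 genes changed 1.5-fold had an adjusted p of 8.05e-12, and 0 of 40 lists of unchanged genes were called. Changed genes and lists were drawn from genes with a mean above 1 CPM, so the shares called do not cover changes at lower levels. Each gene was simulated independently of the others. The simulation therefore does not check the list test where the genes of a list move together, as they did in the real lists.

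Alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, each library left out in turn, stricter thresholds, and the removal of antigen receptor genes and identifiers without a symbol. Counts divided by 4, and the removal of ICR 3 and NOD 2 together, were added after the data were seen. Annotated transcripts with at least 95% identity over at least 200 bases, found with BLAST 2.17.0, were taken as look-alikes of a gene. Where the longest transcript of the gene was short, a shorter alignment was accepted, set by the length of that transcript. Random sets, tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.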

Results

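Polyadenylated RNA was sequenced from 3 samples of ICR mouse and 3 of NOD/Ltj mouse lacrimal glands, the main tear-producing glands of the eye. ICR is an outbred stock and served as the control. NOD/Ltj is an inbred strain with spontaneous autoimmune disease that includes inflammation of tear and salivary glands, and it is used as a model of Sjögren's syndrome. The libraries held 58426580, 76554340 and 62624319 estimated counts in ICR and 63015494, 64000969 and 62318534 in NOD/Ltj, at about 4 counts per fragment. The 20 most abundant genes, many of them secreted tear proteins, took 57.8% ± 6.50 (SD, n = 3) of the counts in ICR and 58.9% ± 4.29 (SD, n = 3) in NOD/Ltj. Ddx3y, carried on the Y chromosome, stood at 57.4 ± 10.3 CPM (counts scaled to library size; SD, n = 3) in ICR and 53.0 ± 11.9 (SD, n = 3) in NOD/Ltj. Xist, made from the inactive X chromosome, stood at 1.36 ± 0.12 and 1.22 ± 0.43 CPM (SD, n = 3 each).

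The comparison asked which transcripts differ between the NOD/Ltj and the ICR gland, with the NF-κB pathway named in the title of the series. B lymphocyte genes headed the transcripts that were higher in NOD/Ltj, and genes of T lymphocytes, antigen presentation and the response to interferon-γ were also higher. Fcer2a, the low-affinity IgE receptor of B cells, rose from 0.106 ± 0.077 to 22.5 ± 16.4 CPM (SD, n = 3 each, adjusted p = 0.0108). Its log2 fold change of 7.75 ranged from 7.03 to 8.48 with 1 library left out and rested on 3, 5 and 11 counts in the ICR libraries. The transcripts that were lower included Prol1, a proline-rich protein of lacrimal secretion (log2 fold change −4.95 ± 0.69 SE, adjusted p = 0.016). Ly6e, a GPI-anchored surface protein, went from 426 ± 232 to 49.0 ± 9.62 CPM (SD, n = 3 each, adjusted p = 0.0211). In a principal component analysis the strains lay on opposite sides of the leading axis, which held 41.8% of the variance. The next axis, with 25.9%, set ICR 1 (−90.3) apart from ICR 2 (64.4) and ICR 3 (55.2).

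Of 18537 genes tested with edgeR, 349 were higher and 67 lower in NOD/Ltj at an adjusted p under 0.05. All 416 had groups that did not overlap, as did 20.05% of all genes tested, where chance gives 10%. These counts moved with single libraries. Without NOD 3 there were 11 higher and 2 lower genes, without NOD 2 63 and 10, without ICR 2 112 and 30, and without ICR 3 120 and 29. Without ICR 1 there were 406 and 118, and without NOD 1 405 and 37. Each of the 416 genes kept its direction in all 6 of these reduced fits, which groups without overlap made nearly certain beforehand. Of the 70 genes called and named by the rule, 3 were called in all 6, namely Cxcl9, Iigp1 and Tgtp2. Another 17 lost their call only without NOD 3, with adjusted p between 0.0509 and 0.0862.

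The B cell genes had the largest median difference of the lists tested with all libraries. Without NOD 2 the salivary gland and skeletal muscle lists had larger ones, in the other direction. Of 21 B cell and germinal centre markers, 13 rose and 8 were not called (16 higher when adjusted over the list alone), with a median 36.6-fold difference. DESeq2 called 16 of them and limma-voom 4. The median was 5.19 on the log2 scale, and 4.58 without NOD 2. Ms4a1, which encodes the B cell antigen CD20, went from 0.307 ± 0.202 to 32.0 ± 16.0 CPM (SD, n = 3 each, adjusted p = 0.0102). Pax5, the transcription factor of B cell identity, rose by 6.37 ± 0.60 (log2, SE, adjusted p = 0.00647), and Ighd, the constant region of IgD, by 6.04 ± 0.62 (log2, SE, adjusted p = 0.0102). Cd22, Fcrl1, Fcmr and Btla, surface receptors of B cells, rose by between 5.77 (Fcmr) and 6.17 (Btla) log2 units. Cr2, a complement receptor of B cells and follicular dendritic cells, rose by 6.12. The 12 largest increases also held Chst3, a chondroitin sulfotransferase (5.83), and Ffar1, a fatty acid receptor, whose 6.93 is uncertain with 0, 4 and 4 counts in the ICR libraries.

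The B cell list passed the camera test at adjusted p = 1.64e-41, with adjusted p = 0.156 with an estimated correlation. Per library, its mean lay 3.12, 4.92 and 4.51 log2 units above the ICR mean in NOD 1, 2 and 3. Without NOD 3 the calls of the named B cell genes ended, with adjusted p from 0.0542 (Pax5) to 0.0781 (Cr2). Chst3 (0.0715) and Ffar1 (0.0963) also lost their calls then. Cr2 and Ffar1 were not called without ICR 2, ICR 3 or NOD 2 either (0.0506 to 0.0801), nor Chst3 without ICR 2 (0.0548). Of the list, 9 members were called without ICR 2 or ICR 3, 8 without NOD 2 and 0 without NOD 3.

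T cell genes followed the same direction. Of 22 T cell markers tested, 14 rose and 8 were not called (21 higher when adjusted over the list alone), with a median 19.3-fold difference. By DESeq2 20 of these markers were called and by limma-voom 2. Cd3e, a chain of the T cell receptor complex, went from 0.339 ± 0.127 to 7.35 ± 2.87 CPM (SD, n = 3 each, adjusted p = 0.0107). Cd3g rose by 4.78 ± 0.61, Lck, the kinase next to the receptor, by 4.28 ± 0.50, and Cd2, an adhesion receptor, by 3.87 ± 0.43 (log2, SE). The co-receptor genes did not pass, Cd4 with a log2 fold change of 4.80 and adjusted p = 0.0761, and Cd8a with 2.83 and adjusted p = 0.0507. The list passed the camera test at adjusted p = 2.90e-43, with adjusted p = 0.156 with an estimated correlation. Without NOD 3 the calls of the 4 named markers that rose ended (0.0665 to 0.0792), and 4, 5, 3 and 0 markers were called without ICR 2, ICR 3, NOD 2 and NOD 3. Cd3g was not called without ICR 3 or NOD 2 either (0.064 and 0.0634), nor Lck without ICR 3 (0.052).

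Among 16 genes of regulatory and helper T cells, 5 rose (10 higher when adjusted over the list alone, 10 by DESeq2 and 0 by limma-voom). They included the checkpoint receptors Ctla4 (4.40 ± 0.74) and Pdcd1 (3.42 ± 0.54), the co-stimulator Icos (3.40 ± 0.49) and the signalling adaptor Sh2d1a (5.97 ± 0.87, log2, SE). The value of Sh2d1a is uncertain, since it rested on 1, 3 and 0 counts in the ICR libraries. The remaining gene was Foxp3, the transcription factor of regulatory T cells (4.12), named after its values were seen, whose call was kept only without NOD 1 among the reduced fits (0.0675 to 0.134 in the others). The median log2 difference of this list was 3.19, or 2.54 with members at 0 in a whole group set at their bound, 2.58 without NOD 2 and 1.44 with the stricter filter. Its camera adjusted p was 2.66e-13, with adjusted p = 0.156 with an estimated correlation. Of 14 cytotoxic and natural killer markers, Ctsw, a cathepsin of cytotoxic lymphocytes, rose by 3.05 ± 0.48 (log2, SE), and 7 were higher when adjusted over the list alone (7 by DESeq2 and 1 by limma-voom). The median difference of these 14 was 2.01 on the log2 scale, or 4.02-fold, and 2.64 on that scale without ICR 1 (camera adjusted p = 6.36e-10, adjusted p = 0.156 with an estimated correlation). Without NOD 2 or NOD 3 the calls of Ctla4, Pdcd1, Icos, Sh2d1a and Ctsw ended (0.085 to 0.139). Ctla4 and Pdcd1 were also not called without ICR 2 or ICR 3 (0.0745 to 0.105), Icos and Ctsw without ICR 2 (0.077 and 0.104), nor Sh2d1a without ICR 3 (0.052). Of the regulatory and helper T cell list, 1 member was called without ICR 2 or ICR 3 and 0 without NOD 2 or NOD 3.

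**Figure D1:**
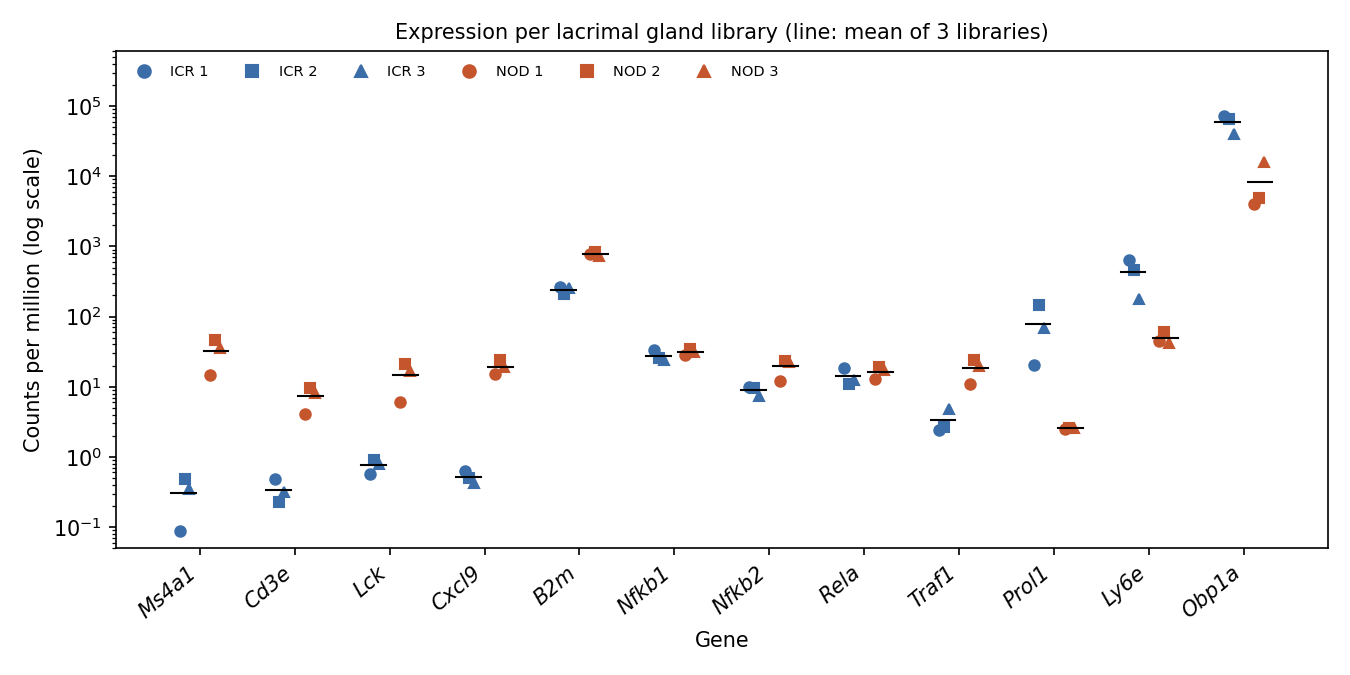
Expression of 12 genes in each of the 6 lacrimal gland libraries, in CPM on a log axis (points, libraries; lines, means of 3). Ms4a1, Cd3e, Lck and Cxcl9 lay under 2 CPM in the ICR libraries and above 4 CPM in the NOD/Ltj libraries, whereas Nfkb1 and Rela overlapped between strains.

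Genes of antigen presentation rose together with the lymphocyte genes. Of 10 genes of MHC class II presentation, 8 rose and all 10 were higher when adjusted over the list alone (10 by DESeq2 and 3 by limma-voom), with a median 9.49-fold difference (3.25 on the log2 scale, and 2.53 without NOD 2). H2-Aa, a chain of the class II molecule, went from 23.1 ± 3.18 to 167 ± 95.7 CPM (SD, n = 3 each, adjusted p = 0.0224). H2-Ob and H2-Oa, which regulate peptide loading in B cells, rose by 4.99 ± 0.69 and 4.98 ± 0.73, and H2-DMb2 by 3.72 ± 0.46 (log2, SE). Of 15 class I genes, 6 rose (8 when adjusted over the list alone, 8 by DESeq2 and 6 by limma-voom), with a median 2.93-fold difference. B2m, the invariant light chain, went from 242 ± 28.8 to 785 ± 45.0 CPM (SD, n = 3 each, adjusted p = 0.016). The peptide transporter Tap1 rose by 2.90 ± 0.36, the class I transactivator Nlrc5 by 3.40 ± 0.44 and H2-Q7 by 4.28 ± 0.58 (log2, SE). The value of H2-Q7 is uncertain, since its family members share sequence and differ between strains.

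Both presentation lists passed the camera test, class II at adjusted p = 7.92e-21 (adjusted p = 0.157 with an estimated correlation) and class I at adjusted p = 6.87e-13 (adjusted p = 0.156 with an estimated correlation). Without NOD 3 the calls of the named genes in both lists ended (0.0715 to 0.109). H2-Aa, H2-Ob, H2-Oa and B2m were also not called without ICR 2, ICR 3 or NOD 2 (0.0556 to 0.105). H2-DMb2 was not called without ICR 2 or ICR 3 (0.0566 and 0.0562), nor were H2-Q7 and Nlrc5 without NOD 2 (0.0684 and 0.0634). The class II list had 5, 1, 0, 1 and 0 members called without ICR 1, ICR 2, ICR 3, NOD 2 and NOD 3. In the class I list 8 were higher and 1 lower without ICR 1. That list had 4, 3, 1 and 0 higher without ICR 2, ICR 3, NOD 2 and NOD 3.

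The interferon-γ response list had 12 of 24 members higher and 12 not called (19 higher when adjusted over the list alone, 18 by DESeq2 and 9 by limma-voom), with a median 5.50-fold difference. Its camera adjusted p was 1.72e-45, with adjusted p = 0.156 with an estimated correlation. Cxcl9, a chemokine that attracts activated T cells, rose 37.5-fold from 0.514 ± 0.101 to 19.4 ± 4.65 CPM (SD, n = 3 each, adjusted p = 0.00139). Its adjusted p was at most 0.024 whichever library was left out. Cxcl10, which binds the same receptor, rose by 3.38 ± 0.32 (log2, SE), a call that ended without NOD 3 (0.0649). The interferon-induced GTPases Iigp1 and Tgtp2 rose by 2.90 ± 0.22 and 3.88 ± 0.33 (log2, SE), where Tgtp2 is uncertain because Tgtp1 is near-identical to it. The list had 17, 8, 7, 5 and 3 members called without ICR 1, ICR 2, ICR 3, NOD 2 and NOD 3.

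Of 29 genes stimulated by type I interferon, 4 rose (14 when adjusted over the list alone, 13 by DESeq2 and 3 by limma-voom), and all 29 had positive fold changes. Among them the antiviral genes Mx1, Rsad2 and Zbp1 rose by 3.42 ± 0.45, 2.15 ± 0.35 and 2.17 ± 0.37 (log2, SE). The median difference of this list was 2.70-fold (camera adjusted p = 1.98e-18, adjusted p = 0.268 with an estimated correlation). The calls of Mx1, Rsad2 and Zbp1 ended without NOD 2 (0.0587 to 0.129) or NOD 3 (0.0715 to 0.123). Rsad2 and Zbp1 were not called without ICR 2, ICR 3 or NOD 1 either (0.064 to 0.12). Of the list, 10 members were called without ICR 1, 2 without ICR 2, ICR 3 or NOD 1, 1 without NOD 2 and 0 without NOD 3.

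NF-κB is a family of transcription factors that drive inflammatory genes, and its subunits did not pass the test adjusted over all genes. Nfkb1 stood at 27.4 ± 4.88 CPM in ICR and 31.5 ± 3.14 in NOD/Ltj (SD, n = 3 each, log2 fold change 0.20 ± 0.19 SE, adjusted p = 0.746). Rela stood at 14.1 ± 3.89 and 16.4 ± 3.05 CPM (SD, n = 3 each, adjusted p = 0.801). The other subunits had larger log2 fold changes that did not pass, Nfkb2 1.13 ± 0.28 (adjusted p = 0.11), Rel 1.19 ± 0.27 (adjusted p = 0.0822) and Relb 1.18 ± 0.49 (SE, adjusted p = 0.365). The inhibitors Nfkbia (0.45 ± 0.30, adjusted p = 0.617) and Tnfaip3 (1.17 ± 0.36, log2, SE, adjusted p = 0.207) did not pass. Neither did the kinase Ikbkb (0.23 ± 0.20, log2, SE, adjusted p = 0.734). Nfkb2 was called without NOD 1 (0.0282), Rel without ICR 3 (0.043) and Tnfaip3 without ICR 1 (0.0218). Rel, Nfkb2 and Tnfaip3 were also higher when adjusted over the list of signalling components alone.

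Of 42 NF-κB signalling components tested, 3 rose and 39 were not called, and 12 were higher and 1 lower (Btrc, −0.67) when adjusted over the list alone. DESeq2 called 11 higher and limma-voom 1, and 17 were higher and 1 lower at an unadjusted p under 0.05. Traf1, an adaptor of TNF receptors and itself an NF-κB target, rose by 2.46 ± 0.38 (log2, SE, adjusted p = 0.0225). Prkcq, the protein kinase C of T cell receptor signalling, rose 3.40-fold (adjusted p = 0.0423). The list had a median log2 fold change of 0.32, or 1.25-fold, and passed the camera test at adjusted p = 2.53e-06, with adjusted p = 0.30 with an estimated correlation. The 20 members under 10 CPM in ICR had a median of 1.15 and the 22 members at or above 10 CPM a median of 0.13. The calls of Traf1 and Prkcq ended without ICR 2, NOD 2 or NOD 3 (0.101 to 0.208), and that of Prkcq also without ICR 3 (0.13) or ICR 1 (0.0636). Of the list, 7 members were called without NOD 1, 5 without ICR 1, 2 without ICR 3 and 0 without ICR 2, NOD 2 or NOD 3.

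Of 39 NF-κB target genes tested, 5 rose and 34 were not called (8 higher when adjusted over the list alone). By DESeq2 13 were higher and by limma-voom 2, with 18 higher and 1 lower at an unadjusted p under 0.05. The chemokine Ccl5 rose by 2.95 ± 0.26 (adjusted p = 0.00543) and the B cell co-stimulator Cd40 by 3.96 ± 0.64 (log2, SE, adjusted p = 0.0251). Ltb, a lymphotoxin needed for lymphoid organ formation, rose by 3.74 ± 0.62 (log2, SE, adjusted p = 0.0278). The others were Cxcl10 and the co-stimulator Cd86 (2.07), the latter named after its values were seen and called only without ICR 1 among the reduced fits (0.0533 to 0.133 in the others). The inflammatory cytokines Tnf (2.63 ± 0.85, adjusted p = 0.231), Il1b (0.31 ± 0.56, adjusted p = 0.888) and Il6 (−0.27 ± 0.65, log2, SE, adjusted p = 0.925) did not pass. Tnf was called without ICR 1 (4.31, adjusted p = 0.0201). Of the targets called with all libraries, Cxcl10 and Ccl5 are also in the chemokine list and Cd40 and Ltb in the TNF superfamily. Cxcl10 is in the interferon-γ list too. The tests of these lists are therefore not independent of each other. The median log2 fold change of the targets was 0.66 (camera adjusted p = 1.07e-07, adjusted p = 0.294 with an estimated correlation), and it was 1.21 without ICR 1 and 1.00 without NOD 1. Ccl5 and Cxcl10 lost their calls without NOD 3 (0.061 and 0.0649), and Cd40 and Ltb in every reduced fit but that without NOD 1 (0.0525 to 0.126). Of the targets, 2 were called without ICR 2, ICR 3 or NOD 2 and 0 without NOD 3. The camera test with its preset correlation also called many lists when the 6 libraries were divided with the strains mixed. Of the 41 lists other than these NF-κB lists, it called 21 between the strains and between 9 and 23 in the 9 mixed divisions. Each mixed division held the strains in unequal shares, so part of the strain difference stayed in it. These counts therefore do not show what the test gives without a strain difference.

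**Figure D2:**
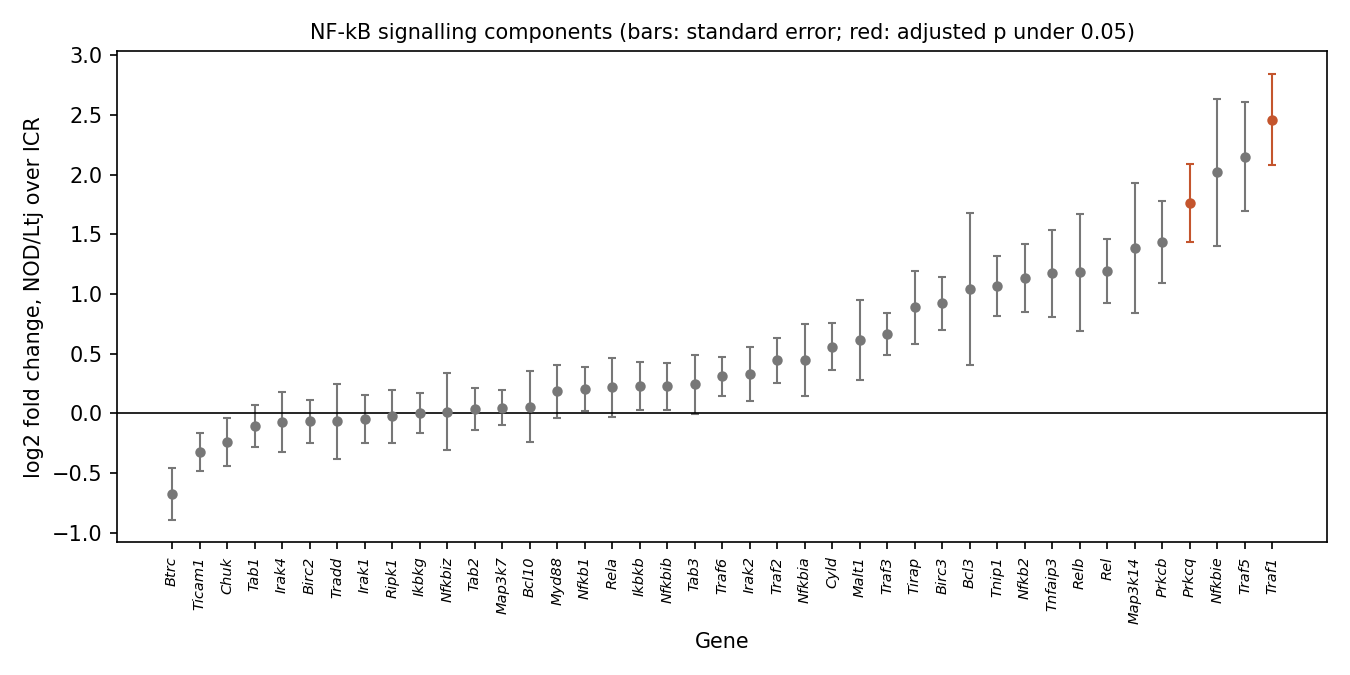
Log2 fold change of 41 of the 42 NF-κB signalling components tested, NOD/Ltj over ICR (points, estimates from 3 libraries per strain; bars, standard error; red, adjusted p under 0.05). Of those shown, Traf1 and Prkcq passed the test, and Nfkb1 and Rela lay at 0.20 and 0.22.

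Genes of lymphoid tissue formation were also higher. Of 13 genes of lymphoid neogenesis and of high endothelial venules, the vessels through which lymphocytes enter lymph nodes, 4 rose (7 when adjusted over the list alone, 7 by DESeq2 and 0 by limma-voom), among them Cr2 and Ltb. Glycam1, a mucin ligand of L-selectin, went from 0.248 ± 0.180 to 8.47 ± 4.95 CPM (SD, n = 3 each, adjusted p = 0.0185). Chst4, a sulfotransferase of these vessels, was at 0 counts in all 3 ICR libraries and at least 2.97-fold higher in NOD/Ltj. The median log2 difference of the list was 3.05, or 2.02 with members at 0 in a whole group set at their bound, 2.40 without NOD 2 and 1.20 with the stricter filter or counts divided by 4 (camera adjusted p = 6.62e-09, adjusted p = 0.232 with an estimated correlation). Ccl19 reached at most 2.18 CPM in a NOD/Ltj library. Ccl21a, another chemokine of lymphoid tissue, held 0, 11 and 44 counts in the NOD/Ltj libraries and 0 in each ICR library.

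Of 41 chemokines and receptors, 7 rose (16 when adjusted over the list alone, 15 higher and 1 lower by DESeq2 and 3 higher by limma-voom), with a median 2.16-fold difference (camera adjusted p = 4.51e-13, adjusted p = 0.163 with an estimated correlation). Cxcr5, the receptor that guides B cells into follicles, rose by 5.13 ± 0.61 (log2, SE). Its ligand Cxcl13 was not called and ranged from 1.71 to 29.3 CPM in ICR and from 9.43 to 49.5 CPM in NOD/Ltj. In the TNF superfamily 6 of 32 genes rose (11 when adjusted over the list alone, 13 by DESeq2 and 0 by limma-voom), including Tnfsf8 (4.44 ± 0.54, with 4, 10 and 11 counts in the ICR libraries) and Tnfrsf4 (2.57 ± 0.38, log2, SE). The median log2 fold change of this family was 1.26, or 2.03 without ICR 3 and 0.45 with counts divided by 4 (camera adjusted p = 6.62e-09, adjusted p = 0.256 with an estimated correlation). Among 25 Toll-like receptor and inflammasome genes 3 rose, as when adjusted over the list alone (4 by DESeq2 and 1 by limma-voom), namely Tlr1 (2.46 ± 0.36), Tlr6 (2.30 ± 0.43) and the DNA sensor Aim2 (2.71 ± 0.42, log2, SE). That list had a camera adjusted p = 9.81e-05, with adjusted p = 0.419 with an estimated correlation. Without NOD 2 or NOD 3 the calls of Glycam1, Chst4, Cxcr5, Tnfsf8, Tnfrsf4, Tlr1, Tlr6 and Aim2 ended (0.0512 to 0.202). Without ICR 2 or ICR 3 those of Chst4, Tnfrsf4, Tlr1, Tlr6 and Aim2 did (0.055 to 0.152). Glycam1 was not called without ICR 3 (0.0912), Chst4 without NOD 1 (0.102), nor Tlr6 without ICR 1 (0.0663). The chemokine list had 4 members called without ICR 2 or ICR 3, 3 without NOD 2 and 1 without NOD 3. The TNF superfamily had 3, 1 and 2 without ICR 1, ICR 2 and ICR 3 and 0 without NOD 2 or NOD 3. The Toll-like receptor list had 5 without ICR 1 and 0 without ICR 2, ICR 3, NOD 2 or NOD 3, and the lymphoid neogenesis list 1 without ICR 2 and 0 without ICR 3, NOD 2 or NOD 3.

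Lists of plasma cells, dendritic cells and other myeloid cells had at most 2 genes each called by edgeR with all libraries. Of 16 plasma cell and immunoglobulin constant genes, 2 rose, Ighm, the constant region of IgM (3.95 ± 0.55, adjusted p = 0.016), and Iglc3, a light chain constant region (3.74 ± 0.56, log2, SE, adjusted p = 0.0189). Igha, Jchain and Igkc had log2 fold changes of 0.92, 0.91 and 1.26 and were not called. When adjusted over the list alone, 4 were higher, with Iglc2 and Ighg3 beside them (4 by DESeq2 and 1 by limma-voom). The median log2 fold change was 1.22 (camera adjusted p = 7.14e-07, adjusted p = 0.329 with an estimated correlation), or 2.99 without ICR 2 and 2.07 with the replicate block. Ighm and Iglc3 lost their calls without ICR 3 (0.0816 and 0.0942) or NOD 3 (0.0828 and 0.0982), Ighm without ICR 2 (0.0843) and Iglc3 without NOD 2 (0.0751), while 4 members were called without ICR 2. Of 12 dendritic cell markers Ccl22, a chemokine of mature dendritic cells, rose by 2.64 ± 0.51 (log2, SE, adjusted p = 0.048), a call that ended whichever library was left out (0.0621 to 0.209). When adjusted over the list alone, 5 of these markers were higher (Ccl22, Itgax, Flt3, Siglech and Il12b) and 1 lower (Cd209a), while DESeq2 called 5 higher and limma-voom 0. The dendritic cell list passed at camera adjusted p = 3.55e-04, with adjusted p = 0.317 with an estimated correlation.

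The 19 monocyte and macrophage markers did not pass (median 0.40, camera adjusted p = 0.0854), and 1, the Fc receptor Fcgr1, was higher when adjusted over the list alone. In these markers ICR 1 lay 1.06 log2 units above the ICR mean. Without it the list median was 1.21 (camera adjusted p = 4.67e-08) and edgeR called 4 members higher. Among these were C1qb, a subunit of complement C1q (adjusted p = 0.022), and Fcgr1 (0.0449). Without NOD 3 the list passed the camera test at 0.0329. The 20 complement genes did not pass (median −0.28, camera adjusted p = 0.857). ICR 1 lay 1.40 above the ICR mean in them. Without it their median was 0.97 (camera adjusted p = 4.54e-05) and edgeR called 3 of them higher. The 8 neutrophil and mast cell markers did not pass either (camera adjusted p = 0.824).

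**Figure D3:**
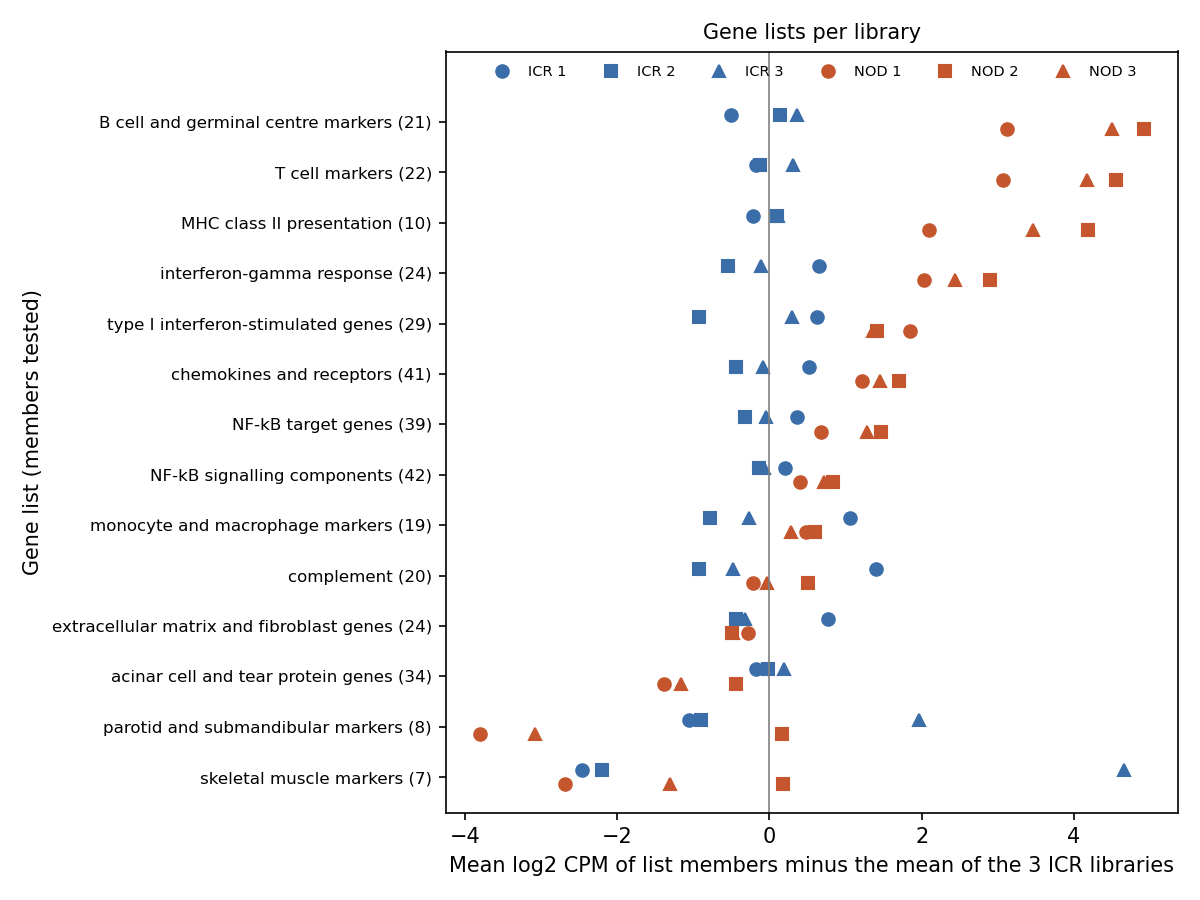
Mean log2 CPM of the members of 14 gene lists in each library, minus the mean of the 3 ICR libraries (points, libraries; number of members tested in brackets). The NOD/Ltj libraries lay at 3.12 to 4.92 in the B cell list, and ICR 3 lay at 4.66 in the skeletal muscle list and at 1.96 in the parotid and submandibular list.

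Genes of the gland itself had fewer calls. Of 34 acinar cell and tear protein genes 1 fell, Prol1, from 78.7 ± 64.0 to 2.55 ± 0.04 CPM (SD, n = 3 each), and 33 were not called. DESeq2 called 1 higher and 5 lower and limma-voom 0. When adjusted over the list alone 3 were lower, Prol1 and the odorant-binding proteins Obp1a (−2.81) and Obp1b (−3.94), which share sequence. Obp1a took 8.55, 5.26 and 3.60% of the counts in ICR 1 to 3 and 0.340, 0.623 and 1.72% in NOD 1 to 3, with adjusted p = 0.11 over all genes. The list had a median log2 fold change of −0.38 (camera adjusted p = 2.57e-04, adjusted p = 0.156 with an estimated correlation). Sval3, a seminal vesicle antigen-like secretory protein, went from 480 ± 308 to 45.3 ± 16.8 CPM (SD, n = 3 each, adjusted p = 0.0443). Odam, an odontogenic ameloblast-associated protein, fell by 3.04 and Slc15a2, a peptide transporter, fell by 2.33 on the log2 scale (adjusted p = 0.0483 and 0.0454). Card14, a scaffold protein that activates NF-κB in epithelia, went from 14.9 ± 10.5 to 0.372 ± 0.172 CPM (SD, n = 3 each, adjusted p = 0.0116). The non-coding RNA Snhg11 had a log2 fold change of −3.15 ± 0.44 (SE, adjusted p = 0.016). Rasd2, Plekha4 and AC123702.1 had log2 fold changes of −3.62, −2.89 and −4.71.

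The calls of these lower genes ended in some of the reduced fits, which held fewer libraries. Without NOD 3 those of Prol1, Ly6e, Sval3, Odam, Slc15a2, Card14, Snhg11, Rasd2, Plekha4 and AC123702.1 ended (0.0862 to 0.236), and without NOD 2 all of these but Rasd2 (0.055 to 0.157). Odam was called in none of the 6 reduced fits. Sval3 and Slc15a2 were not called without ICR 2, ICR 3 or NOD 1 (0.0809 to 0.148), Prol1 without ICR 3 or NOD 1 (0.0551 and 0.0559), nor Ly6e without ICR 2 or NOD 1 (0.077 and 0.0736). Plekha4 was not called without ICR 2 or ICR 3 (0.0866 and 0.09), Snhg11 without ICR 3 (0.055), nor AC123702.1 without ICR 2 (0.0553).

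Cwc22, a splicing factor, went from 428 ± 389 to 16.5 ± 1.31 CPM (SD, n = 3 each, adjusted p = 0.0164), a call that ended without NOD 1, NOD 2 or NOD 3 (0.0591, 0.101 and 0.113). It has near-identical annotated copies, and the sum over Cwc22 and these 7 copies was 490 ± 442 CPM in ICR and 17.1 ± 1.23 in NOD/Ltj (SD, n = 3 each). Of the 67 lower genes, 23 had another lower gene within 1 Mb, against a median of 6 in random gene sets of like expression, and of the 349 higher genes 201 had another higher gene within 1 Mb, against 136. Of these 23, 12 had look-alikes in the transcript annotation, with Cwc22 and each of its copies counted as separate genes. For C130026I21Rik and Gm16028, which fell and were named after their values were seen, the sum over their copies was 0.24 and 0.09 log2 units higher in NOD/Ltj. C130026I21Rik was called only without ICR 1 among the reduced fits (0.103 to 0.246 in the others), and Gm16028 was not called without NOD 2 or NOD 3 (0.0612 and 0.08).

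Other lists of gland function had 1 gene called by edgeR between them. Of 22 ductal and ion transport genes 0 were called by edgeR (4 at an unadjusted p under 0.05, all lower, 1 by DESeq2 and 0 by limma-voom). This list passed the camera test with a median of −0.44 (adjusted p = 0.0152, adjusted p = 0.419 with an estimated correlation), though not without ICR 1 (0.105) or NOD 1 (0.104). Its member with the smallest p was the water channel Aqp4 (−0.78 ± 0.19, log2, SE, adjusted p = 0.105). Among 27 genes of secretagogue receptors and calcium signalling, Itpr2, an intracellular calcium channel, rose by 1.72 ± 0.32 (log2, SE, adjusted p = 0.0434). Of the reduced fits only that without NOD 1 kept this call (0.0566 to 0.193 in the others). When adjusted over this list alone 4 were higher, among them Itpr2, Prkcd and Atp2a3, and 1 lower (Prkca), the same numbers as by DESeq2 against 0 by limma-voom, and the list did not pass (camera adjusted p = 0.522). The 31 exocytosis genes (0.524), the 11 myoepithelial markers (0.0941) and the 21 genes of the unfolded protein response (0.829) did not pass the camera test. The myoepithelial list passed without ICR 1 (0.0322) or NOD 2 (0.0342).

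Markers of stroma and of tissue next to the gland differed between single libraries. In 24 extracellular matrix and fibroblast genes ICR 1 lay 0.77 log2 units above the ICR mean, and 0 genes were called by edgeR, DESeq2 or limma-voom (4 at an unadjusted p under 0.05, all lower). The list had a median of −0.41 (camera adjusted p = 0.0145, adjusted p = 0.679 with an estimated correlation), or −0.05 without ICR 1 (0.483). Dcn, a collagen-binding proteoglycan, stood at 693, 111 and 119 CPM in the ICR libraries. The 10 adipocyte markers had a median of −1.40 (adjusted p = 0.00367, adjusted p = 0.552 with an estimated correlation) and did not pass without ICR 1 (−0.60, 0.105) or NOD 1 (0.112), and their median was −2.37 without NOD 2. The 8 parotid and submandibular markers, genes of the neighbouring salivary glands, had a median of −2.12 (adjusted p = 0.0291, adjusted p = 0.567 with an estimated correlation). Without ICR 3 their median was 0.07 (0.313) and without NOD 2 −5.78, and they did not pass without NOD 1 (0.13) or NOD 3 (0.0505). ICR 3 also lay 4.66 log2 units above the ICR mean in 7 skeletal muscle markers (median −3.79, camera adjusted p = 0.139). The muscle list passed without ICR 1 (0.00403) or ICR 2 (0.00364), and its median was 0.58 without ICR 3 (0.304) and −5.24 without NOD 2.

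Mitochondrially encoded transcripts took 8.04, 3.02 and 4.40% of the counts in ICR 1 to 3 and 2.70, 3.90 and 2.91% in NOD 1 to 3. Their list of 13 had a median of −0.86 (camera adjusted p = 2.77e-06, adjusted p = 0.419 with an estimated correlation), or −0.51 without ICR 1. Of these, 7 were lower at an unadjusted p under 0.05, 0 were called by edgeR, 5 by DESeq2 and 0 by limma-voom. The 30 nuclear genes of oxidative phosphorylation passed with a median of −0.16 (adjusted p = 0.0311, adjusted p = 0.634 with an estimated correlation), but not without ICR 1, ICR 2, NOD 2 or NOD 3 (0.0589 to 0.095). Rps2 rose by 2.14 ± 0.18 (log2, SE, adjusted p = 0.0047, and 0.0509 without NOD 3), a value made uncertain by its many processed copies. The 29 ribosomal protein genes it belongs to did not pass (camera adjusted p = 0.258, and 0.0118 without ICR 3).

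Timp3, an inhibitor of matrix proteases, fell by 0.86 on the log2 scale (adjusted p = 0.0392), a call kept only without ICR 1 among the reduced fits (0.0745 to 0.239 in the others). The 19 cathepsins and matrix proteases did not pass (camera adjusted p = 0.0914, and 0.0133 and 0.00682 without ICR 2 and ICR 3), and Timp3 and Ctsl were lower when adjusted over the list alone. Bcl2, an inhibitor of apoptosis, rose by 1.49 ± 0.28 (log2, SE, adjusted p = 0.0446), a call kept only without NOD 1 (0.0634 to 0.21 in the others). The 23 apoptosis genes did not pass (camera adjusted p = 0.152, and 0.0296 without ICR 1). Neither did the 25 cell cycle genes (0.139, and 3.16e-04 without ICR 1) or the 13 immediate early and heat shock genes (0.14, and 0.0344 without ICR 2). The endothelial (0.95), Harderian and sebaceous gland (0.348), nerve and Schwann cell (0.0721) and erythrocyte lists (0.829) did not pass the camera test, nor did the sex-linked (0.878), hormone receptor (0.401) and cholesterol and fatty acid synthesis lists (0.156). The endothelial genes Pecam1 and Vwf were higher, and the hormone receptor gene Thra lower, when adjusted over their lists alone. Of the 330 members tested in the 20 lists that did not pass, 4 were called, Timp3, Itpr2, Bcl2 and Rps2. In 3 of these lists, the neutrophil and mast cell, secretagogue and unfolded protein response lists, the median, the mean and the direction of the test did not all share a sign.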

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

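Chosen only after the data were seen were the division of counts by 4 and the removal of ICR 3 and NOD 2 together, the libraries with the most transcripts of salivary gland and muscle. The 349 higher and 67 lower genes became 940 and 279 with DESeq2, which included all of them, and 123 and 20 with limma-voom, of which 120 and 20 were shared. An adjusted p under 0.01 left 21 and 7. With each library left out in turn, the counts ranged from 11 (without NOD 3) to 406 (without ICR 1) higher and from 2 (without NOD 3) to 118 (without ICR 1) lower genes. Without ICR 3 and NOD 2 together, edgeR called 2 higher and 0 lower genes, with 1117 and 627 at an unadjusted p under 0.05. Other scalings, filters, the division by 4 and the removal of antigen receptor genes gave 324 to 407 and 57 to 75. Each of the 349 and 67 genes kept its direction in every alternative that tested it, which groups without overlap made nearly certain beforehand. The reduced fits held fewer libraries, and for the other changes the cause was not tested.

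A fit with the replicate block called 129 higher and 25 lower genes, of which 122 and 25 were shared. Nothing in the labels says that samples of the same number are pairs, so the numbers were not taken as pairs. Samples of the same number deviated with correlations of −0.12, −0.149 and 0.0723, too few values to decide on pairing.

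The NF-κB signalling components, with a median of 0.32, had an adjusted p of 0.30 with an estimated correlation and of 0.0579 by fry, and the NF-κB targets, with a median of 0.66, of 0.294 and 0.0656. With each library left out in turn, camera with its preset correlation kept both lists past the threshold, with medians from 0.27 to 0.43 and from 0.47 to 1.21. Of the other lists, 21 passed (18 to 23 with a library left out), against 0 with an estimated correlation (9 of all 43 lists at an unadjusted p under 0.05) and 9 by fry. The complement list ranged from −0.61 (without ICR 3) to 0.97 (without ICR 1) and among these passed upward only without ICR 1, and the cause was not tested. The parotid and submandibular list lost its call without a filter (0.0735), with the stricter filter (0.0594) and with counts divided by 4 (0.0606). Without a filter the skeletal muscle (0.0274) and nerve and Schwann cell lists (0.043) passed, the latter also by fry (0.0366), and without ICR 3 and NOD 2 the cathepsin (0.00685) and ribosomal protein lists (0.00335) did. That removal also moved the medians of the interferon-γ (1.87), class II (2.58), lymphoid neogenesis (2.12), adipocyte (−2.13), salivary (−3.53) and muscle lists (0.05), and the replicate block those of the latter 2 (−3.17 and −2.07). Of the 106 named genes 70 were called with the main settings, so at most 70 could lose a call. All 70 lost it without ICR 3 and NOD 2. Among these 70, 44 lost it with limma-voom, 31 with the block, and up to 67 with 1 library left out (NOD 3). With DESeq2 10 of the named genes not called before gained a call. Depth limited genes near 0.2 CPM, where 1 library holds about 3 fragments.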

Other observations

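Chosen only after the results were seen were the symbol families, the tests on tissue sources and scaling of the lymphocyte genes, the test of neighbouring genes, and the sums over copies for parts of the clustered lower genes. The genes named for these stems and the abundant genes beside them were also chosen after their values were seen.

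Genes sharing a symbol stem were tested for an excess of called genes with Fisher's exact test (1044 tests, Benjamini-Hochberg adjusted), and 7 stems passed, the broad Cd, H and Il stems among them. Of the guanylate-binding protein genes, GTPases of cell-autonomous immunity, 7 of 11 were higher in NOD/Ltj (adjusted p = 8.50e-08), with Gbp8 at 0.657 ± 0.492 and 16.7 ± 7.39 CPM (SD, n = 3 each). Of the Gimap genes, GTPases of lymphocytes, 6 of 9 were higher (adjusted p = 8.92e-07), with Gimap3 at 4.84 ± 0.55 and Gimap4 at 4.33 ± 0.52 (log2, SE). The Ifi stem, which includes the DNA-binding Ifi200 family, had 6 of 18 higher (adjusted p = 1.14e-04), with Ifi209 at 4.03 ± 0.43 (log2, SE). The Slamf receptors had 3 of 5 (adjusted p = 0.0096), with Slamf6 at 5.40 ± 0.63 (log2, SE). Gene copies within these families may share reads and lie together, so their members are not independent. Without NOD 3 none of these calls remained, and without NOD 2, ICR 2 or ICR 3 fewer did (1, 3 and 3 of the 7 Gbp genes, and 2, 1 and 3 of the 6 Gimap genes). Without NOD 1 3 of the 6 Ifi genes and 2 of the 3 Slamf genes stayed called, and without ICR 1 5 of the 6 Gimap genes.

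Some of the most abundant transcripts had large differences that did not pass the edgeR test. Obp1a stood at 58890 ± 17220 CPM in ICR and 8375 ± 6793 in NOD/Ltj (SD, n = 3 each, adjusted p = 0.11). The mucin-like Mucl2 stood at 57690 ± 35490 and 14180 ± 3352 CPM (SD, n = 3 each, adjusted p = 0.171), and Mup4, a major urinary protein, at 22350 ± 2676 and 42580 ± 15990 CPM (SD, n = 3 each, adjusted p = 0.474).

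The first pattern is the higher B and T lymphocyte genes. Salivary gland tissue taken with the gland was argued against, since the lowest NOD/Ltj library exceeded the highest ICR library by at least 2.75 log2 units in both lists while a NOD/Ltj library lay below every ICR library in the salivary list. Scaling set by a few abundant genes was argued against too, since a scaling factor moves all genes of a library alike, while the median log2 fold change of each list lay at least 4.30 above that of all genes tested. RNA of an attached lymph node and lymphocytes within the gland cannot be told apart, since Ccl19 reached 2.18 CPM and no lymph node library was at hand to set the level it should reach. Between the strains, edgeR called 349 higher and 67 lower genes. The other 9 splits had 0 and 0 as their highest (160 to 1874 at an unadjusted p under 0.05). Each of those splits held the strains in unequal shares, so part of the strain difference stayed in it. Thus 1 of 10 splits gave values as large, and 10 splits are too few for a share under 0.05.

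Lower genes lying close together are the next pattern. Of the 67, 23 had another lower gene within 1 Mb, Cwc22 and its 7 copies among them. The random sets of like expression had a median of 6 and a highest value of 21 in 10000 (permutation p = 1e-04, the smallest they can give). Cwc22 and its copies entered this count as 8 separate genes, though the counting could split reads among them. The test was not run without the copies, so its p-value treats them as independent. The 349 higher genes also lay together, 201 of them against a median of 136 and a highest value of 176 (permutation p = 1e-04), and missing gene copies in NOD/Ltj would not raise genes. For the 23 lower genes, strain variants or missing gene copies and shared regulation cannot be told apart, since genes of both directions clustered. Reads shared between near-identical copies were tested only in the 12 of the 23 that had look-alikes. In 10 of these 12 the sum over all copies lay below every ICR library, a smaller share than the one set beforehand for excluding sharing, so it stays open for the 12 as a set, whose parts went different ways. Of the 10, 8 were Cwc22 and its copies with 1 common sum, which differed by −4.83 on the log2 scale and argues against sharing there. C130026I21Rik and Gm16028 were picked because their sums did not lie below every ICR library. The larger of these sums differed by 0.24, which that choice made likely beforehand, so it is no separate support for sharing. Reads shared between copies stay a candidate explanation for them.

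The last pattern is the NF-κB signalling components. The members under 10 CPM in ICR had a median 1.02 log2 units above that of the others. In 10000 random sets of like level the median was 0.02 and the highest value 0.78 (permutation p = 1e-04, the smallest they can give). RNA of infiltrating lymphocytes was predicted to give such a difference. The members under 10 CPM also included Traf1 (3.31 CPM in ICR), itself an NF-κB target. Induction of such members in gland cells could give the same difference, so the split does not tell these explanations apart. The random sets drew each gene on its own. The permutation p-value therefore takes no account of genes that move together, or of the spread between samples. Induction in gland cells was not tested and stays open. The NF-κB targets were not split by level in this way. The −log10 p of the list was 6.08, with 5.67 as the highest of the other splits, and for the targets 7.53 with 6.22, so 1 of 10 splits was as large in both. Of the other lists 21 were called, with 23 as the highest (ICR 1, ICR 2 and NOD 1 against the rest), so 2 of 10 splits were as large, and 10 splits are too few for a share under 0.05.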
